A study of Drosophila melanogaster with 33 samples.

How the data were processed

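RNA was measured in staged fruit fly embryos injected with 250 or 50 mM 5-ethynyl uridine. Each preparation gave an eluate of the streptavidin pull-down, a flow-through and an input, sequenced after the SMARTer Stranded kit, per the labels' protocols. The authors deposited values for 21 poly(A) libraries and, separately, for 12 rRNA-depleted libraries, with 16407 genes in each set. STAR, HTSeq and the dm6 genome build are named without versions per the submitters' processing notes; filters, annotation, strand setting and scaling are not given in the sources used here. Both tables are named RPKM by the authors. The deposited RPKM values are, as the values themselves show, reads per kilobase times an unknown factor per library, plus 1: a gene without a read stands at exactly 1, and after taking off 1 the low values fall on whole multiples of 1 step per library, within a tolerance of 0.02, in most genes. The column totals differ between libraries and are lower in eluates than in inputs (1.30 to 3.75 against 14.9 to 33.2, in units of 1000000, in the poly(A) set).

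From those steps and the exonic lengths, the reads per library were estimated at 1.93 M to 36.9 M (M, 1000000). In poly(A) libraries they were 4.23 M to 27.8 M in eluates, 1.93 M to 36.9 M in flow-throughs and 6.45 M to 21.2 M in inputs. These are estimates, so no count test was run and no counting interval is given. Reads from both strands may share a gene where genes overlap, and near-identical copies, such as the replication-dependent histones, the Bob genes and RpS14a with RpS14b, may share reads, so values of such genes are uncertain. Gene symbols were matched to the BDGP6.54 annotation (release 115), 16320 of 16407 (99.47%) by current symbol or synonym; coordinates, lengths and introns come from it. The gene zld is Zelda, also called vfl. Every column was tied to 1 sample by its stage, fraction, dose and replicate. The aborted transcripts and retained introns named in the series title need reads along genes and were not analysed here.

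The design had planned tests on the values as deposited. Since 1 had been added and the scaling of each library is unknown, the added 1 was taken off, each library was scaled to 1000000 (ppm) and then by the median of ratios to the geometric mean over genes, and that rescaled fit was used instead; the fit of the values as deposited is given as the alternative. Genes at 1 or more in at least 2 libraries of a table were tested, 8618 in the poly(A) and 8034 in the rRNA-depleted set. Values were tested as log2(value + 1), so a fold change understates the change of low genes, with limma (empirical Bayes with a mean trend, adjusted p below 0.05 after Benjamini-Hochberg over all genes tested). All 21 poly(A) libraries entered 1 fit with a mean per stage and fraction, so that groups of 2 shared an estimate of the spread; comparisons over all stages had a term for stage. NC 7-9, and single stages of the rRNA-depleted set, had 1 library per group and no test. The tables were never tested together.

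The comparisons were eluate against input at 3 stages and over all stages, in both tables; flow-through against input; eluate and input between stages; the difference in enrichment between stages; and the difference between 250 and 50 mM. The 2 doses differ within syncytial and cellular blastoderm only, where the replicate number differs with them. Eluate, flow-through and input of 1 stage, dose and replicate number in the titles are 1 preparation. Checked on the values, their deviations from the stage mean correlated across genes at 0.594 to 0.65 between eluate and input. The range was 0.589 to 0.929 between flow-through and input and 0.513 to 0.676 between eluate and flow-through, so the titles pair the fractions. The main fit does not use this pairing. The fit with the preparation as a block is given where it changes a call or moves a count by more than 1.5 times. The 2 libraries of each stage and fraction had a Pearson r of 0.919 to 0.972 and no gene with identical values in both.

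The 22 gene lists were written from textbook knowledge: gap, terminal and head genes, pair-rule, segment polarity with Hox, dorsoventral patterning, sex determination with dosage compensation, cellularisation with cell cycle slowing, Bearded with Enhancer of split, and early zygotic short genes of less known function. Then came maternally loaded patterning with germ plasm, maternal cell cycle with egg activation, maternal transcription factors with chromatin pioneers, cytoplasmic ribosomal proteins, and housekeeping with cytoskeletal genes. The others were replication-dependent histones, histone variants, mitochondrially encoded genes, small non-coding RNA, heat shock and stress, and markers of follicle cells, pole cells, yolk, hemocyte and amnioserosa cells, and older embryo tissues. They were tested with camera at the preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. Of 175 list tests camera called 97, none with an estimated correlation, and fry 87. The lists tested for dose are counted apart. A NC 7-9 list was set against 10000 random lists matched on expression. Lengths were compared by permutation (100000 resamples, two-sided) and intronless shares by Fisher's exact test, adjusted over 10 comparisons of each kind.

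Genes were named by rule: per comparison and direction, from the 12 with the largest called change, a level of 5 or more in the higher group and no overlap between groups (for all stages, the same sign in every preparation); from up to 4 members of each list with the largest change, called or not; and from bcd, nos, CycB, sisA, sc, zen, twi, sna, nullo, bnk, slam, ftz, eve, hb, zld and RpL32. The text names a part of those, and some items are not reported here. Groups, comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter or a filter of 5, values as deposited, no mean trend, at least 2-fold, the preparation block, flow-through as comparator, 250 mM libraries alone and each library left out; added later were scaling by the total alone, leaving out the second NC 9-10 preparation, leaving out the doubted rRNA-depleted inputs, and exonic length.

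The code was tested on simulated data with 200 changed genes per comparison. The changed genes were picked at random and the spread was drawn independently per library, without the link between fractions of 1 preparation. These rates therefore check the code and need not hold for the real data. For eluate against input at NC 9-10 it recovered 13.4% of 67 genes at a log2 change of 1, 70.1% of 67 at 2 and 93.9% of 66 at 4, with 3 false calls among 8618 genes; over all stages it recovered 50.7%, 91.0% and 100% with 2 false calls, and in the rRNA-depleted set 4.5%, 65.7% and 97.0% with 8 false calls among 8034. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.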

Results

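Fruit fly embryos of the Oregon R wild-type strain were injected with 5-ethynyl uridine (5-EU), a uridine analogue that cells build into RNA made after the injection. The embryos were staged by their shape into nuclear cycles (NC) 7-9, NC 9-10, syncytial blastoderm and cellular blastoderm. Labelled RNA was biotinylated and pulled down on streptavidin beads, so that each preparation gave an eluate (RNA made after the injection, plus background), a flow-through (unbound RNA) and an input (total RNA). The series asks which transcripts the embryo's own genome makes in the earliest nuclear cycles, when nearly all of its RNA still comes from the mother. There were 21 poly(A) libraries from 7 preparations (1 at NC 7-9 and 2 at each later stage) and 12 rRNA-depleted libraries (1 preparation per stage). All preparations had 250 mM 5-EU except the second poly(A) preparation at syncytial and at cellular blastoderm, which had 50 mM. The read number per library, estimated from the steps between low values, ran from 1.93 M to 36.9 M (M, 1000000 reads).

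Eluates held far less RNA per library in the deposited values than inputs. Higher or lower below means after rescaling, not always against the bulk of genes. On the values as deposited, the median gene lay at log2 −4.29 in eluate against input at NC 9-10, −3.74 at syncytial blastoderm, −1.91 at cellular blastoderm, −3.42 over all stages and −5.22 in the rRNA-depleted set. The corresponding shift was −0.28 for flow-through against input. Between cellular blastoderm and NC 9-10 it was 0.93 for eluates and −0.76 for inputs, and between syncytial blastoderm and NC 9-10 eluates it was 0.19. The shift of the difference in enrichment from NC 9-10 was 1.62 at cellular and 0.52 at syncytial blastoderm. After rescaling, the median gene still lay at 0.55 in eluate against input at cellular blastoderm. Levels below are rescaled values in parts per 1000000 (ppm). The p-values of single stages measure only the spread between preparations, which at syncytial and cellular blastoderm also differ in dose. Over all stages the p-values also take in differences of enrichment between stages. In the rRNA-depleted set, with 1 preparation per stage, those differences and the spread between preparations cannot be told apart. The labels do not tie preparations to separate collections of embryos.

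At NC 7-9, the earliest stage, a short list of genes stood out in the labelled RNA: X-linked sisA, a counting element of sex determination, the cellularisation gene bnk, the proneural gene amos, the short early genes CG13713, CG13712 and dunk, and several genes of the mitochondrial genome. The gene sisA (FBgn0003411, X chromosome, 11321579 to 11322357, minus strand, 779 bp without an intron) was at 10.4 in the poly(A) eluate and 0.184 in the input, a log2 ratio of 3.27 after adding 1 to both. For bnk the levels were 7.00 and 0.14, and CG13713 was at 8.26 in the eluate and listed at 0 in the input. Mitochondrial mt:ND2, a subunit of respiratory complex I, was at 374 against 91.6. With 1 library per group there was no test, and a rule of size was used. By it, 17 of 8618 genes in the poly(A) set and 50 of 8034 in the rRNA-depleted set were at least 2-fold above both input and flow-through with an eluate level of at least 5. More genes lay at least 2-fold below both, 34 and 144 with an input or flow-through level of at least 5. Of the 7897 genes in both sets, 10 met the rule in both (sisA, CG13712, CG13713, dunk, mt:CoI, mt:ND2, mt:ND4, mt:ND4L, mt:ND5 and mt:ND6), where 0.108 would be shared by independent lists. The titles give both sets the same preparation name at NC 7-9, so they may come from the same embryos and are not independent. The poly(A) count was 9 on values as deposited, and 49 or 6 with an eluate minimum of 1 or 20.

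As groups at NC 7-9, the early zygotic short genes of less known function (34 tested, 6 meeting the rule) had a median log2 eluate over input of 0.76, and the mitochondrially encoded genes (15 tested, 6 meeting it) of 1.37. Both medians were above all of 10000 random lists of the same size matched on expression, at a percentile of 100. The sex determination list had a median of 0.60 (percentile 99.98) and the gap, terminal and head genes 0.04 (percentile 99.65). The latter were near the floor (median level 0.12 in the eluate and 0 in the input). Their random lists ran from −0.012 to 0, so a small value above 0 ranked high. In rRNA-depleted RNA neither of these 2 lists stood out: the sex determination list was at 0.13 (percentile 96.7), inside the range of the random lists, and the gap, terminal and head genes at 0.00 (percentile 6.4, 5 of 15 above 0). The older embryo tissue list, a marker of another stage, also stood high in poly(A) RNA (median 0.10, percentile 99.8). The cytoplasmic ribosomal protein genes lay below every random list with a median of −0.44. These percentiles describe 1 eluate and 1 input and carry no replicate error.

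**Figure D1:**
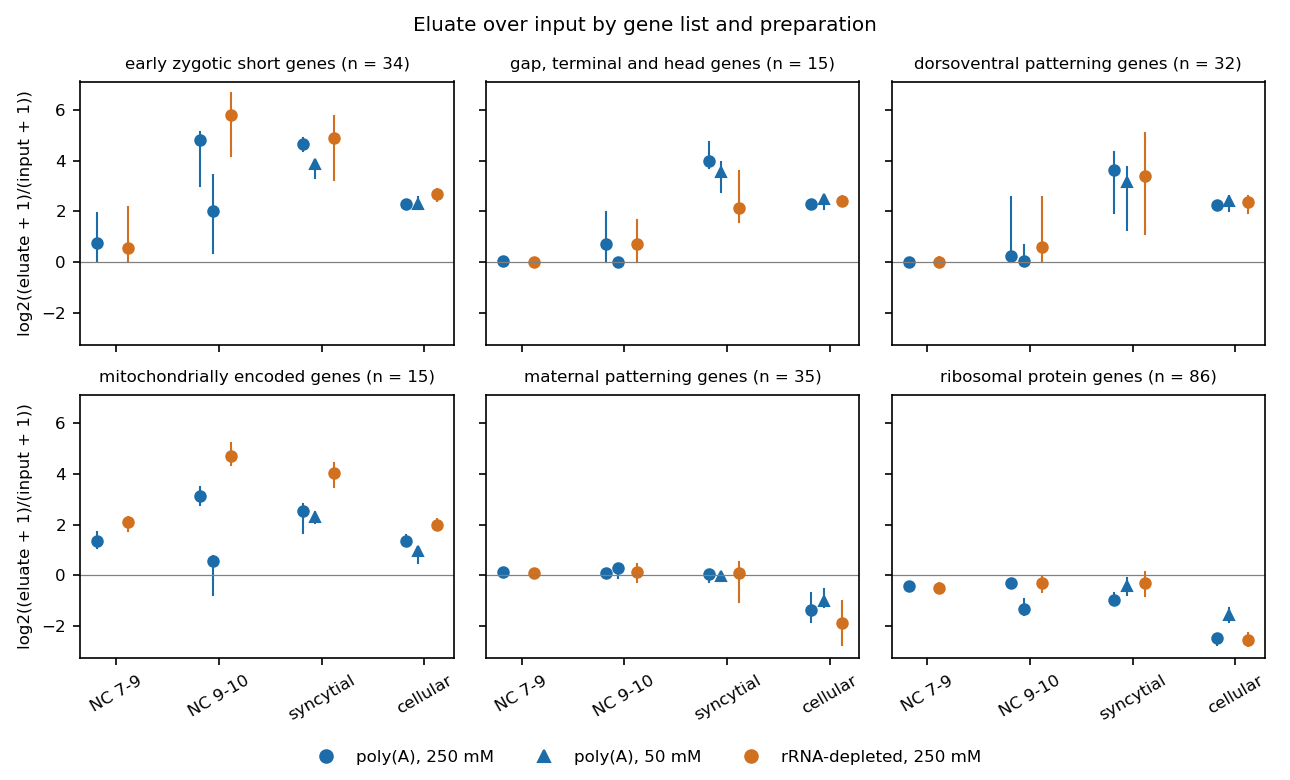
Median log2((eluate + 1)/(input + 1)) of 6 gene lists (vertical axis) by stage (horizontal axis), 1 point per preparation, with bars from the lower to the upper quartile over the genes of the list. Early zygotic short genes were at 0.76 at NC 7-9 in poly(A) RNA and at 4.81 and 2.02 in the NC 9-10 preparations, while ribosomal protein genes lay below 0 in every preparation. On values as deposited, where all genes together lie at −3.42 over all stages, the all-stage median is 0.15 for early short genes and −1.98 for mitochondrial genes.

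At NC 9-10 the listed genes measured furthest above input in the eluate were again short zygotic genes, but no gene passed the test over all genes. The log2 difference (n = 2 against 2) was 4.90 ± 0.77 (SE) for sisA, 4.99 ± 0.79 for CG18269 and 4.72 ± 0.67 for CG16815, short early genes of less known function, each at adjusted p = 0.0866. The level of sisA was 122 ± 107 (SD, n = 2) in the eluate and 2.57 ± 2.05 in the input. Further values above input came from nullo, which shapes the cellularisation furrow (4.63 ± 0.92, adjusted p = 0.167), and the dorsal homeobox gene zen (3.37 ± 0.68, 0.178). The pair-rule gene eve (3.52 ± 0.72, 0.181), the mesoderm regulator sna (3.42 ± 0.70, 0.181) and Tom, a Bearded-family inhibitor of Notch signalling (3.02 ± 0.52, 0.106), measured above input too. Maternal transcripts lay near 0: bcd, the anterior determinant, was at 0.13 ± 0.21, nos, the posterior one, at 0.04 ± 0.34 and the mitotic cyclin CycB at 0.08 ± 0.19 (adjusted p = 1 for each). The segment polarity gene hh was at 0.20 ± 0.47 and the complex I gene mt:ND2 at 2.83 ± 0.69 (adjusted p = 0.324).

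Adjusted over the list alone, more of these genes passed: 22 of 34 early zygotic short genes (median 3.26), 7 of 15 mitochondrial genes (1.83) and 6 of 32 dorsoventral genes (0.19), all higher. So did 5 of 8 sex determination genes (2.86), 5 of 10 cellularisation genes (2.87), 5 of 11 Bearded and Enhancer of split genes (1.55) and 4 of 9 pair-rule genes (2.29), again all higher. Camera placed these lists above the other genes (adjusted p from 7.83e-37 to 4.43e-08), and each call was lost with an estimated correlation (adjusted p = 0.0966 to 0.271 with an estimated correlation). Of 15 gap, terminal and head genes, none passed adjusted over the list alone. Their median was 0.30 (camera 0.00122; adjusted p = 0.346 with an estimated correlation). The segment polarity and Hox list had a median of 0.00 (camera 0.727), and among the maternal lists the patterning and germ plasm genes were at 0.13 (camera 0.0289; adjusted p = 0.476 with an estimated correlation). Ribosomal protein genes lay below input with a median of −0.80 and 1 of 86 above 0, none called (camera 3.53e-22; adjusted p = 0.336 with an estimated correlation). So did 19 small non-coding RNA genes (median −0.59, camera 0.0444, 0.0522 with the preparation block; adjusted p = 0.502 with an estimated correlation).

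Limma called 0 of 8618 genes at NC 9-10 (smallest adjusted p 0.0866), while 135 were higher and 261 lower at an unadjusted p below 0.05. With the preparation as a block 24 were higher and 14 lower, among them sisA and CG18269 (adjusted p = 0.0129 for both), CG16815 and Tom (0.0344), nullo, eve, run, Elba3, CG14317, CG14427 and Ocho (0.0454) and Brd (0.0472). As deposited, 1 was higher and 6785 lower. Without the first eluate 5 genes were called and without the second 36. The 2 preparations differed: the median enrichment of the 34 early zygotic short genes was 4.81 in the first and 2.02 in the second, and that of the 15 mitochondrial genes 3.12 and 0.58.

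At syncytial blastoderm, when the zygotic genome is widely transcribed, most of the listed patterning genes of the embryo were higher in the labelled RNA. The gap gene kni was at log2 4.50 ± 0.62 (SE, n = 2 against 2; adjusted p = 0.000404), and tll, which patterns the termini, at 4.49 ± 1.15 (0.0226). The pair-rule genes eve, run and ftz were at 4.42 ± 0.72 (0.00132), 4.68 ± 1.17 (0.0197) and 4.27 ± 1.12 (0.0262). Segment polarity genes were higher too: ptc, the Hedgehog receptor, was at 4.02 ± 0.38 (5.71e-05), and the signalling genes wg and hh were at 3.52 ± 0.36 (7.9e-05) and 2.81 ± 0.47 (0.00147). Along the dorsoventral axis zen was at 4.76 ± 0.68 (0.000542), sna at 4.23 ± 0.70 (0.00149) and twi, which specifies mesoderm, at 3.97 ± 1.11 (0.0367). The BMP pathway genes scw, tsg and tld were at 4.64 ± 1.23 (0.0275), 4.52 ± 1.03 (0.0113) and 4.42 ± 0.78 (0.00224). The level of zen was 1513 ± 478 (SD, n = 2) in the eluate and 53.7 ± 3.32 in the input.

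Other early genes were higher at syncytial blastoderm as well. They included sisA (4.57 ± 0.77, adjusted p = 0.00161), the proneural X-linked element sc (4.23 ± 1.14, 0.0295), the cellularisation genes nullo (4.27 ± 0.92, 0.00791) and bnk (4.33 ± 1.02, 0.0135). So were halo, which steers lipid droplets (4.28 ± 0.91, 0.00755), and Elba3, a subunit of an early insulator complex (4.65 ± 1.05, 0.011). The cell death genes rpr and skl were at 4.42 ± 0.42 (5.88e-05) and 3.85 ± 0.43 (0.000122), and the snoRNA host genes Uhg5 and Uhg1 at 3.44 ± 0.47 (0.000392) and 2.56 ± 0.52 (0.00534). Of the mitochondrial genes, mt:CoI, a subunit of cytochrome oxidase, was at 2.41 ± 0.57 (0.0142). The transcription factor grh (3.16 ± 0.56, 0.00229) and gcm, a regulator of hemocytes and glia (2.21 ± 0.51, 0.0124), were higher too. The maternal transcripts bcd (−0.29 ± 0.21, 0.515), nos (0.06 ± 0.34) and CycB (0.03 ± 0.19, 0.981) did not pass. Among the 62 lower genes were plu, a subunit activating the PAN GU kinase of the early cycles (−1.72 ± 0.43, 0.0206), and the non-coding CR46147 (−3.14 ± 0.64, 0.0059). Also lower were PGAP3, of GPI-anchor maturation (−2.35 ± 0.69, 0.0452), and Tmem18 (−2.28 ± 0.65, 0.0396).

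By list at syncytial blastoderm, all 9 pair-rule genes were higher, 12 of 15 gap, terminal and head genes, 24 of 32 dorsoventral genes and 8 of 14 segment polarity and Hox genes, with none lower. So were 7 of 8 sex determination genes, 8 of 10 cellularisation genes, 8 of 11 Bearded and Enhancer of split genes and 31 of 34 early zygotic short genes, again with none lower. Adjusted over the list alone the counts were 9, 14, 25, 9, 7, 9, 9 and 33. Their medians ran from 1.24 (segment polarity and Hox) to 4.28 (early short genes), and camera called each of them (adjusted p from 1.89e-17 to 1.63e-05; adjusted p = 0.144 to 0.213 with an estimated correlation). Of the mitochondrial genes 8 of 15 were higher, 11 adjusted over the list alone (median 2.41, camera 4.51e-05; adjusted p = 0.435 with an estimated correlation). Of the heat shock and stress genes 5 of 15 were higher, 7 adjusted over the list alone (median 0.91, camera 0.046, 0.0836 with the preparation block; adjusted p = 0.232 with an estimated correlation). Besides the cell death genes rpr and skl, Hsp23, a small heat shock chaperone (2.47 ± 0.74, 0.0498), and Thor, which controls translation (2.42 ± 0.52, 0.00755), were higher.

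Few members of the maternal lists passed at syncytial blastoderm. Of 35 patterning and germ plasm genes 1 was higher, the torso pathway gene tsl (1.21 ± 0.30, adjusted p = 0.0184), and none adjusted over the list alone (median 0.01, camera 0.143). Of 27 cell cycle and egg activation genes 1 was lower, plu, and none adjusted over the list alone (median −0.09, camera 0.0223; adjusted p = 0.405 with an estimated correlation). Of 15 maternal transcription factors and chromatin pioneers 2 were higher, also adjusted over the list alone (median 0.56, camera 0.235, 0.00127 with the preparation block). Of the same list zld, the main activator of the early genome, measured 1.73 ± 2.12 (adjusted p = 0.777, 0.000108 with the preparation block). Its eluate levels were 126 in the first and 19.5 in the second preparation, against inputs of 33.2 and 5.96. None of 86 ribosomal protein genes was called, also adjusted over the list alone (median −0.70, camera 5.22e-12; adjusted p = 0.482 with an estimated correlation). With the preparation block 17 were lower, among them RpL41 (−1.54 ± 0.74, 0.275 without the block and 0.0315 with it) and RpS14b (−1.71 ± 0.70, 0.177 and 0.0216), which shares sequence with a near copy. None of the 23 housekeeping genes (median −0.09), 2 replication-dependent histone genes (0.93), 6 histone variants (−0.24), 3 follicle cell genes (−0.08) or 8 pole cell genes (−0.12) was called. Of the rest, 2 of 19 small non-coding RNA genes (0.00), 1 of 3 yolk, hemocyte and amnioserosa genes (2.21) and 1 of 14 older embryo tissue genes (0.55) were higher, with the same counts adjusted over the list alone. Camera called none of these. With the preparation block the maternal cell cycle list had 1 higher, CycE (0.88 ± 0.32, adjusted p = 0.111, 0.00228 with the block), and 4 lower, among them alphaTub67C (−0.66 ± 0.32, 0.273 and 0.0153). It had 6 higher maternal transcription factors, lola among them (0.76 ± 0.34, 0.229 and 0.00863), 2 higher yolk, hemocyte and amnioserosa genes, with srp, a GATA factor (2.43 ± 1.29, 0.333 and 0.000421), and 5 higher older embryo tissue genes. With that block the neuronal gene elav (1.54 ± 0.69, adjusted p = 0.232) passed at 0.0108, as did the kinase partner CycT (1.54 ± 0.78, 0.307) at 0.000367 and Sod1, which removes superoxide (−1.03 ± 0.51, 0.286), at 0.0364.

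In all, limma called 972 genes higher and 62 lower of 8618 at syncytial blastoderm. In 682 of the higher and 46 of the lower, the level was 5 or more and the libraries of the 2 fractions did not overlap. No overlap either way is what chance gives in 33.3% of genes in a given comparison of 2 against 2. With the preparation block the counts were 1313 and 369, on values as deposited 71 and 6340, and on values scaled by their total alone 852 and 399. Without the first or the second input the total of 1034 became 639 or 659.

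At cellular blastoderm, when membranes close around the nuclei, labelled RNA was higher for a wide set of zygotic genes and lower for most ribosomal protein transcripts and part of the maternal ones. The gene slam, needed for membrane growth, was at log2 2.57 ± 0.38 (SE, n = 2 against 2; adjusted p = 0.000265), with levels of 10210 ± 480 (SD, n = 2) in the eluate and 1714 ± 10.6 in the input. The Hox genes Dfd and abd-A were at 2.46 ± 0.56 (0.0031) and 2.18 ± 0.34 (0.000349), the segmentation regulators opa and bowl at 2.41 ± 0.37 (0.000332) and 2.50 ± 0.31 (0.000126), and ptc at 2.39 ± 0.38 (0.000377). Dosage compensation genes were higher, with msl-2 at 2.69 ± 0.60 (0.00271) and the non-coding roX1 at 2.51 ± 0.68 (0.00793), and so was trbl, which slows the cell cycle (2.56 ± 0.37, 0.000255). The maternal transcripts bcd (−1.30 ± 0.21, 0.000391), nos (−1.10 ± 0.34, 0.0154), the germ cell gene pgc (−2.07 ± 0.53, 0.00588), dhd, a thioredoxin of the egg (−2.09 ± 0.27, 0.000139), and png, the PAN GU kinase (−2.23 ± 0.48, 0.00235), were lower.

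Non-coding, mitochondrial and tissue genes passed at cellular blastoderm as well. The non-coding CR45940 and CR45153 had log2 differences of 4.09 ± 0.32 (adjusted p = 3.55e-05) and 3.67 ± 0.60 (0.000449), and the small RNA gene scaRNA:MeU2-G25 2.99 ± 0.72 (0.00414). The dorsoventral genes tld, tok and zen were higher by 2.73 ± 0.78 (0.011), 2.57 ± 0.34 (0.000158) and 2.52 ± 0.68 (0.00827), and the pair-rule gene eve by 2.18 ± 0.72 (0.0224). The earliest genes sisA (2.30 ± 0.77, 0.0236) and nullo (2.35 ± 0.92, 0.0463) passed as well, while bnk (2.41 ± 1.02, 0.0613) and sc (2.50 ± 1.14, 0.0816) passed with the preparation block only (0.0127 and 0.0357). Genes of differentiated tissues were higher: elav (2.23 ± 0.69, 0.0163) and the chitin genes serp (2.42 ± 0.45, 0.000919) and Gasp (2.39 ± 0.53, 0.00272). Mitochondrial mt:ND4 was at 1.82 ± 0.66 (0.0344) and mt:CoI at 1.45 ± 0.57 (0.0469, 0.0905 with the preparation block). Lower genes included GstD1, a detoxifying enzyme (−2.92 ± 0.47, 0.000427), Sod1 (−2.49 ± 0.51, 0.00165), the glycolytic gene Gapdh2 (−2.38 ± 0.42, 0.000671). The nuclear genes UQCR-11 and mRpL33 of mitochondrial respiration and translation (−3.14 ± 0.72, 0.00344, and −2.92 ± 0.46, 0.000374) were lower too, as was scu, a mitochondrial dehydrogenase (−2.97 ± 0.57, 0.00114).

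By list at cellular blastoderm, all 14 segment polarity and Hox genes, 27 of 32 dorsoventral genes, 13 of 15 gap, terminal and head genes and 17 of 34 early zygotic short genes were higher, and none was lower. Adjusted over the list alone the counts were 14, 29, 13 and 10, and 27 early short genes were higher with the preparation block. Camera called these lists (medians 1.85, 2.35, 2.44 and 2.25; adjusted p 0.000627, 8.39e-05, 0.0169 and 0.0194), each lost with an estimated correlation (adjusted p = 0.605 to 0.76 with an estimated correlation). It did not call the pair-rule list (6 of 9 higher, 6 adjusted over the list alone) or the sex determination list (6 of 8, 6). Nor did it call the cellularisation list (5 of 10, 3) or the Bearded and Enhancer of split list (4 of 11, 4). None of their genes was lower (camera 0.0853 to 0.264 for the 4 lists). Of the ribosomal protein genes 82 of 86 were lower, 85 adjusted over the list alone (median −2.05, camera 1.56e-24; adjusted p = 0.605 with an estimated correlation), such as RpL39 (−2.87 ± 0.57, 0.00141), RpL41 (−2.86 ± 0.74, 0.00641) and RpL32 (−2.37 ± 0.64, 0.00775). On values as deposited the ribosomal protein median lay at −2.83 relative to that of all genes, and on values scaled by their total alone it was −2.15.

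Among maternal lists, 21 of 35 patterning and germ plasm genes were lower and 3 higher (23 and 3 adjusted over the list alone; median −1.14). Of these snk and spz, a protease and the ligand of the Toll pathway, were at −2.31 ± 0.42 (adjusted p = 0.000811) and −1.93 ± 0.49 (0.00582). Camera gave 5.6e-06 for that list and 0.0169 for the 27 cell cycle and egg activation genes, of which 9 were lower and 5 higher, also adjusted over the list alone (median −0.46). Both calls were lost (adjusted p = 0.605 with an estimated correlation). The higher members included Cks85A, a partner of cyclin-dependent kinases (2.13 ± 0.58, 0.00834), and the checkpoint kinase mei-41 (2.04 ± 0.40, 0.00131). Housekeeping genes were lower in 12 of 23 and higher in 3 (13 and 3 adjusted over the list alone; median −0.76, camera 0.00106; adjusted p = 0.605 with an estimated correlation). The maternal transcription factor list had 4 of 15 higher, among them pan, the effector of Wg signalling (2.22 ± 0.36, 0.000469), and da, a partner of proneural proteins (2.20 ± 0.36, 0.000439), and 1 lower, also adjusted over the list alone (median 0.68, camera 0.898).

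The remaining lists at cellular blastoderm were not called by camera. Of the heat shock and stress genes 7 of 15 were higher and 3 lower (8 and 3 adjusted over the list alone), with Hsp68 at 2.19 ± 0.27 (adjusted p = 0.000115), hid at 2.04 ± 0.76 (0.0376) and skl at 2.29 ± 0.43 (0.00108). Small non-coding RNA genes were higher in 3 of 19 (3 adjusted over the list alone), with the host gene Uhg5 at 2.01 ± 0.47 (0.00377). Mitochondrial genes were higher in 2 of 15 (0 adjusted over the list alone; median 1.11, and as deposited −1.58, or 0.33 relative to all genes). Histone variants were higher in 1 of 6, the centromere histone cid (2.06 ± 0.33, 0.000438), and lower in 2, one of them His2Av (−1.58 ± 0.25, 0.000392), with 1 and 3 adjusted over the list alone. Of 2 replication-dependent histone genes 1 was higher, also adjusted over the list alone. Among markers of other cells, pole cell genes were lower in 5 of 8 and higher in 1, also adjusted over the list alone (zpg, a germline gap junction gene, −1.84 ± 0.24, 0.000144; Tre1, a receptor guiding germ cells, 2.16 ± 0.28, 0.000153). Of the follicle cell list 1 of 3 was higher (Yp3, a yolk protein gene, 1.55 ± 0.31, 0.0014), of the yolk, hemocyte and amnioserosa list 1 of 3 (gcm, 1.92 ± 0.51, 0.00745), and of the older embryo tissue list 8 of 14 (camera 0.185, 0.0497 with the preparation block), with the same counts adjusted over the list alone.

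Limma called 3328 genes higher and 1517 lower at cellular blastoderm, with 2809 and 1456 of them at a level of 5 or more and free of overlap between the fractions. With the preparation block the counts were 4040 and 2133, and on values as deposited 61 and 4371. Of the 972 genes higher at syncytial blastoderm 870 were higher at cellular blastoderm. Of the 62 lower, 22 were lower again, and none of the 972 was lower. Both stages share each gene's estimate of spread, so no overlap by chance is given.

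**Figure D2:**
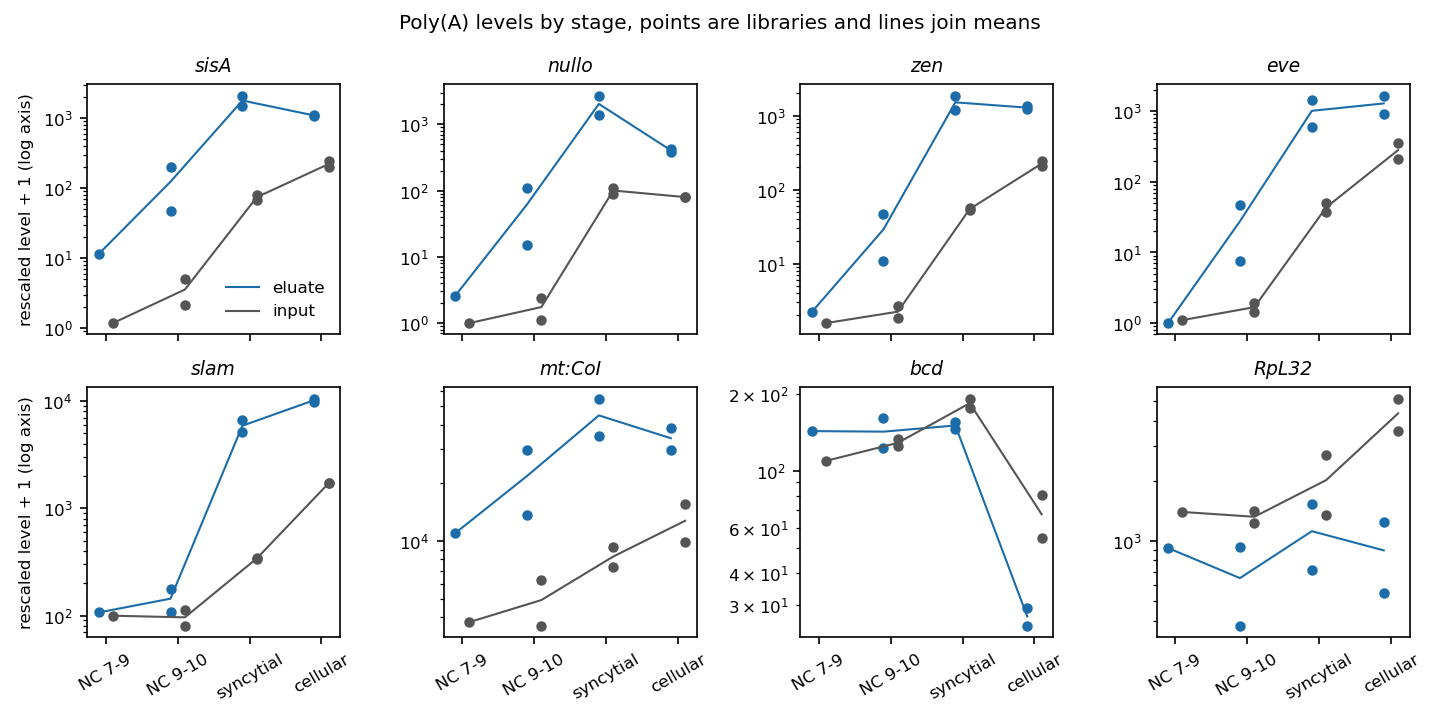
Rescaled poly(A) level plus 1 (vertical axes, log scale, ppm, range set per panel) of 8 genes in eluate and input by stage (horizontal axis); points are libraries and lines join the means. Eluate levels of sisA went from 10.4 at NC 7-9 to 1779 ± 417 (SD, n = 2) at syncytial blastoderm, while bcd was at 26.0 ± 3.11 in the cellular blastoderm eluate and 66.6 ± 18.3 in the input.

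Over all 7 poly(A) preparations, genes named by rule with a high ratio of eluate over input included sisA (log2 3.83 ± 0.50, SE, n = 7 against 7; adjusted p = 0.00143), CG18269 (3.68 ± 0.49, 0.00143), dunk (3.68 ± 0.57, 0.00411), CG13712 (3.65 ± 0.59, 0.00465) and amos (3.62 ± 0.72, 0.0122). Other high values were those of bnk (3.47 ± 0.54, 0.00411) and nullo (3.41 ± 0.61, 0.00751). The dorsal genes tsg (3.29 ± 0.59, 0.00743), zen (3.11 ± 0.51, 0.00491) and zen2 (3.35 ± 0.56, 0.00517) were higher, as were sc (3.08 ± 0.62, 0.0137), run (3.26 ± 0.66, 0.0137), eve (2.87 ± 0.60, 0.0152) and Tom (2.96 ± 0.44, 0.00411). Mitochondrial transcripts were higher, with mt:ND2 at 2.47 ± 0.38 (0.00411), mt:ND4 at 2.25 ± 0.36 (0.00465) and mt:CoI at 1.92 ± 0.32 (0.00517). Nearer the threshold were wg (1.64 ± 0.51, 0.0427), grh (1.61 ± 0.53, 0.0474), rpr (1.80 ± 0.56, 0.0424) and ptc (1.84 ± 0.58, 0.043, 0.0501 with the preparation block). Lower were RpL41 (−1.71 ± 0.41, 0.0245), RpL39 (−1.58 ± 0.35, 0.02) and RpL32 (−1.34 ± 0.35, 0.0321). So were the nuclear-encoded mitochondrial genes ND-B15 (−2.01 ± 0.61, 0.0409), mRpL33 (−1.71 ± 0.33, 0.0122) and mRpS21 (−1.77 ± 0.55, 0.0427). The egg activation genes png (−1.41 ± 0.27, 0.0115), plu (−1.26 ± 0.30, 0.0248) and dhd (−0.90 ± 0.28, 0.0416) were lower as well. The maternal transcripts bcd (−0.36 ± 0.21, 0.205), nos (−0.27 ± 0.23, 0.395) and CycB (0.07 ± 0.12, 0.654) did not pass.

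As groups over all stages, 31 of 34 early zygotic short genes, 9 of 9 pair-rule genes, 21 of 32 dorsoventral genes, 11 of 15 gap, terminal and head genes and 12 of 15 mitochondrial genes were higher with none lower (33, 9, 27, 14 and 12 adjusted over the list alone). Of the ribosomal protein genes 69 of 86 were lower with none higher (83 adjusted over the list alone). Camera called 14 of 22 lists, these 6 among them (adjusted p from 1.05e-36 to 1.35e-05), and all were lost (adjusted p = 0.231 to 0.382 with an estimated correlation). With the preparation block it also called the maternal transcription factors (median 0.42, camera 0.138 without the block and 0.0076 with it) and the older embryo tissue genes (0.64, 0.0723 and 0.00811), a marker of another stage, and both were lost (adjusted p = 0.306 and 0.391 with an estimated correlation). The ribosomal protein median was −1.08, and on values as deposited −4.77, or −1.35 relative to all genes. The mitochondrial median was 1.71, and as deposited −1.98, or 1.44 relative to all genes. Limma called 911 genes higher and 515 lower, 284 and 384 of them at a level of 5 or more and in the same direction in every preparation. With 250 mM libraries alone, fewer samples, none was called. As deposited, these were 19 and 6890, and on values scaled by their total alone 618 and 1038. Without single libraries the total of 1426 ran from 85 (without the second cellular blastoderm input) to 2261 (without the NC 7-9 eluate).

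In rRNA-depleted RNA, with 1 preparation per stage, the listed genes measured furthest above input were short zygotic and mitochondrial genes, and no gene passed. Over the 4 stages the log2 difference (n = 4 against 4) was 5.16 ± 0.76 (SE) for CG13712, 5.00 ± 0.81 for CG18269, 4.94 ± 0.71 for CG34214 and 4.38 ± 0.69 for sisA, each at adjusted p = 0.0909. Mitochondrial mt:ND2 and mt:ND4L were at 4.46 ± 0.62 and 4.37 ± 0.73 (0.0909), tsg at 4.49 ± 0.83 (0.124), zen at 3.54 ± 0.90 (0.311) and the linker histone gene His1:CG33834, of a repeated family, at 2.91 ± 0.90 (0.36). The histone value rests on 2 doubted inputs: the list's median was 3.07 and 5.70 at NC 9-10 and syncytial blastoderm, whose inputs resemble poly(A) libraries, against −0.87 at NC 7-9 and 1.54 at cellular blastoderm. Below input lay RpL23A (−2.11 ± 0.66, 0.36), RpL28 (−1.75 ± 0.45, 0.312) and gnu, of the PAN GU kinase (−2.39 ± 0.66, 0.36), while bcd was at −0.75 ± 0.52 (0.444). The level of sisA in the eluate went from 12.7 at NC 7-9 to 247, 5292 and 2204 at the later stages, against 0.376, 2.40, 108 and 416 in the input.

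Adjusted over the list alone, 27 of 34 early zygotic short genes (median 3.57), 13 of 15 mitochondrial genes (3.21), 6 of 10 cellularisation genes, 6 of 10 Bearded and Enhancer of split genes and 5 of 8 sex determination genes were higher in rRNA-depleted eluates. These medians lean on the 2 stages whose inputs resemble poly(A) libraries: early short genes were at 5.79 and 4.90 there against 0.55 and 2.70 at NC 7-9 and cellular blastoderm, and mitochondrial genes at 4.71 and 4.03 against 2.12 at NC 7-9 and less at cellular blastoderm (percentile 99.01, 13 of 15 above 0). Camera called 14 of 21 lists, among them the 86 ribosomal protein genes (median −0.90, camera 2.9e-20, none called singly), and all were lost (adjusted p = 0.361 to 0.453 with an estimated correlation). Limma called 0 of 8034 genes (smallest adjusted p 0.0909), with 519 higher and 554 lower at an unadjusted p below 0.05, and 47 without the NC 7-9 preparation. As deposited, 3 were higher and 6941 lower. The inputs labelled rRNA-depleted at NC 9-10 and syncytial blastoderm resembled poly(A) libraries (Pearson r of 0.996 and 0.989 across genes with a poly(A) input; the other 10 libraries reached 0.942), and without them the count was again 0. By stage, the rule of size counted 50, 196, 1147 and 3024 genes from NC 7-9 to cellular blastoderm, and the rank correlation of enrichment with poly(A) RNA across genes, which are not independent replicates, was 0.478, 0.216, 0.359 and 0.936.

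**Figure D3:**
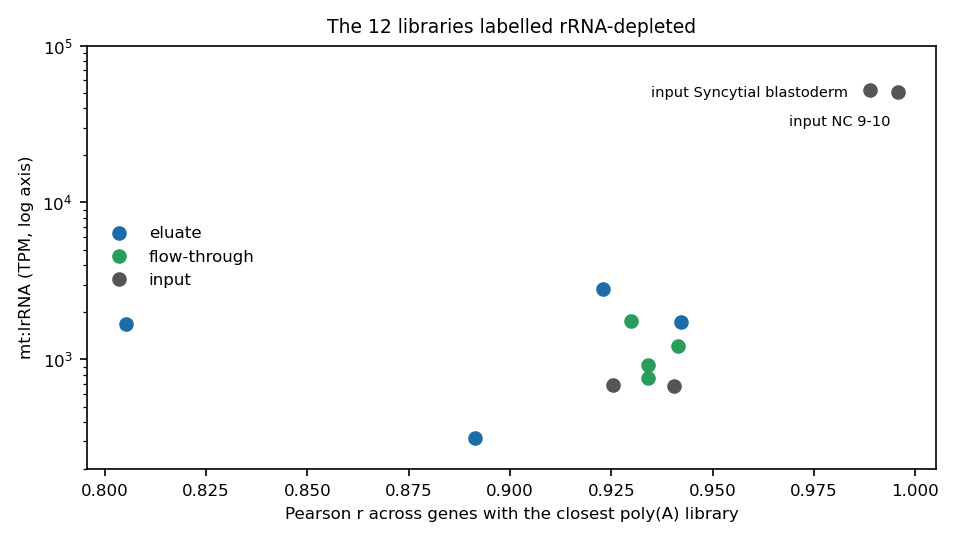
Level of the mitochondrial large ribosomal RNA, mt:lrRNA (vertical axis, ppm, log scale), against the Pearson correlation across 7269 genes with the closest poly(A) library (horizontal axis) for the 12 libraries labelled rRNA-depleted, coloured by fraction. The inputs of NC 9-10 and syncytial blastoderm sit apart at 50320 and 51700 ppm. The other 10 libraries lie between 315 and 2821.

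The unbound RNA was compared with the input as a control of the pull-down. Zygotic genes measured below input there without passing: sc at log2 −1.70 ± 0.62 (SE, n = 7 against 7), scw at −1.59 ± 0.76, CG15382 at −1.61 ± 0.76, amos at −1.52 ± 0.72, nullo at −1.39 ± 0.61 and sisA at −0.92 ± 0.50. The maternal bcd was at −0.04 ± 0.21, nos at 0.08 ± 0.23, dhd at 0.47 ± 0.28 and RpS30 at 0.66 ± 0.29 (adjusted p = 1 for each). The early zygotic short genes had a median of −0.95, also below 0 on values as deposited (−1.43), and ribosomal protein genes one of 0.20, which was −0.03 as deposited. Limma called 0 of 8618 genes, also with the preparation block and on values as deposited, with 48 higher and 26 lower at an unadjusted p below 0.05.

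The deposited values of eluate and flow-through can be set side by side within a preparation as the share of a gene found in the eluate, if both fractions were scaled alike. For sisA that share was 78.6% at NC 7-9, 84.1% and 92.8% at NC 9-10, 96.7% and 73.4% at syncytial blastoderm and 59.9% and 55.7% at cellular blastoderm (first and second preparation). The median share of the early zygotic short genes was 74.9%, then 83.9% and 56.8%, 95.5% and 71.9%, and 73.0% and 59.0%. For ribosomal protein genes the median share ran from 2.08% to 6.97%. Eluate plus flow-through summed to between 61.8% and 132% of the poly(A) input. The eluate made up only 3.82% to 15.3% of that sum, so the sum mainly checks the flow-through. The scaling of the eluate, on which these shares depend, is not checked by it.

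Between NC 9-10 and cellular blastoderm, many zygotic transcripts rose in the labelled RNA, and part of the maternal ones fell. The largest rises were in Ptr, a Patched-related protein (log2 11.30 ± 0.64, SE, n = 2 against 2; adjusted p = 5.72e-08), Dtg, a target of Dpp (10.80 ± 0.56, 3.46e-08), and opa (10.39 ± 0.37, 9.38e-09). Their eluate levels at cellular blastoderm were 2900 ± 249 (SD, n = 2) for Ptr and 1426 ± 379 for opa. The segmentation genes ptc (9.59 ± 0.38, 1.13e-08), kni (8.94 ± 0.62, 2.37e-07) and Kr (8.11 ± 0.43, 3.78e-08) rose, as did roX1 (8.49 ± 0.68, 6.72e-07), rpr (7.25 ± 0.42, 6.95e-08) and twi (7.47 ± 1.11, 0.00011). Rises were also found for grh (6.57 ± 0.56, 1.23e-06), elav (5.64 ± 0.69, 2.26e-05), gcm (4.86 ± 0.51, 6.49e-06), zen (5.82 ± 0.68, 1.62e-05) and sisA (3.48 ± 0.77, 0.0021). Transcripts laid down in the egg fell, among them dhd (−7.10 ± 0.27, 1.13e-08), the germ plasm organiser osk (−5.14 ± 0.36, 2.76e-07), and the piRNA cluster factor del (−7.19 ± 0.83, 1.46e-05). The small heat shock gene Hsp26 (−5.68 ± 0.30, 3.76e-08), the meiotic regulator mtrm (−5.40 ± 0.25, 2.02e-08), the maternal tubulin alphaTub67C (−5.45 ± 0.32, 7.16e-08) and zpg (−5.61 ± 0.24, 1.42e-08) fell too. So did Gapdh2 (−6.81 ± 0.42, 9.32e-08), nos (−3.92 ± 0.34, 1.31e-06), bcd (−2.39 ± 0.21, 1.31e-06) and the embryonic linker histone BigH1 (−4.37 ± 0.88, 0.00105). CycB fell by 0.59 ± 0.19 on the log2 scale (0.019) and RpL32 did not pass (0.48 ± 0.64, 0.545).

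By list, 31 of 32 dorsoventral genes, 29 of 34 early zygotic short genes, 14 of 15 gap, terminal and head genes and 14 of 14 segment polarity and Hox genes rose in the eluate. So did 9 of 9 pair-rule genes, 9 of 11 Bearded and Enhancer of split genes, 8 of 8 sex determination genes and 8 of 10 cellularisation genes. The counts were 31, 30, 14, 14, 9, 9, 8 and 8 adjusted over the list alone. In these lists 1 early short gene fell, and 1 gap gene did adjusted over the list alone. Maternal patterning and germ plasm genes fell in 27 of 35 and rose in 1 (27 and 1 adjusted over the list alone; median −2.37). Pole cell genes fell in 7 of 8 and rose in 1, also adjusted over the list alone (median −3.59), while maternal cell cycle genes fell in 13 of 27 and rose in 8, also adjusted over the list alone (median −0.53). Camera called these 11 lists (adjusted p from 4.65e-12 to 0.0102), each lost (adjusted p = 0.123 to 0.52 with an estimated correlation). Ribosomal protein genes rose in 3 of 86, none adjusted over the list alone (median 0.09, but −0.56 on values scaled by their total alone; camera 0.174), and none of the 15 mitochondrial genes passed (median 0.65). Limma called 3343 genes higher and 1552 lower. As deposited, these were 2990 and 690, and on values scaled by their total alone 2460 and 2499.

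At syncytial blastoderm, zygotic transcripts were likewise higher in the eluate than at NC 9-10, and some maternal ones lower. The Sox gene D rose by 8.73 ± 0.66 on the log2 scale (SE, n = 2 against 2; adjusted p = 3.63e-06), Ppa, an F-box gene, by 8.76 ± 0.70 (4.41e-06), and geko by 9.05 ± 0.93 (2.46e-05). Rises of kni by 8.14 ± 0.62 (3.69e-06), Kr by 7.42 ± 0.43 (1.56e-06), ptc by 6.90 ± 0.38 (1.47e-06), halo by 7.91 ± 0.91 (6.13e-05), zen by 6.03 ± 0.68 (5.27e-05) and sisA by 4.17 ± 0.77 (0.00189) passed too. Falls were smaller: the RNA-binding gene hoip was at −5.12 ± 0.46 (1.06e-05) and cort, which activates the anaphase-promoting complex in the egg, at −3.11 ± 0.37 (8.52e-05). The thioredoxin gene dhd fell too (adjusted p = 1.01e-05). Then came exu, which localises bcd RNA, at −2.94 ± 0.33 (5.19e-05) and the germline helicase vas at −1.82 ± 0.30 (0.000961). Neither bcd (0.09 ± 0.21, 0.815) nor CycB (0.23 ± 0.19, 0.462) passed, and nos (−1.01 ± 0.34) was at 0.0536, or 0.0467 with the preparation block. Of the lists, 33 of 34 early zygotic short genes, 24 of 32 dorsoventral genes, 12 of 15 gap, terminal and head genes and 9 of 9 pair-rule genes rose (33, 25, 13 and 9 adjusted over the list alone). Maternal patterning genes fell in 7 of 35 and rose in 1 (8 and 1 adjusted over the list alone). Camera called 13 lists, each lost (adjusted p = 0.192 to 0.785 with an estimated correlation). Limma called 1172 higher and 638 lower. As deposited, these were 546 and 124, and on values scaled by their total alone 969 and 1282. Without the second NC 9-10 preparation the total of 1810 became 906.

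In total poly(A) RNA, without any pull-down, many zygotic transcripts also rose from NC 9-10 to cellular blastoderm, and part of the maternal ones fell. The zygotic genes CG13427 (log2 10.59 ± 0.85, SE, n = 2 against 2; adjusted p = 2.18e-06), Inx3, a gap junction gene (9.50 ± 0.61, 5.92e-07), opa (7.92 ± 0.37, 2.23e-07), kni (7.75 ± 0.62, 2.16e-06) and eve (7.36 ± 0.72, 9.1e-06) rose. So did ptc (7.35 ± 0.38, 2.23e-07), ftz (7.21 ± 1.12, 0.000262), sna (6.86 ± 0.70, 1.26e-05), twi (6.70 ± 1.11, 0.000412) and zen (6.67 ± 0.68, 1.24e-05). The early genes sisA (6.08 ± 0.77, 5.67e-05), nullo (5.62 ± 0.92, 0.00037), slam (4.18 ± 0.38, 5.15e-06) and sc (4.01 ± 1.14, 0.012) rose. The level of eve went from 0.680 ± 0.349 (SD, n = 2) to 281 ± 96.4. Maternal dhd fell by 5.48 ± 0.27 on the log2 scale (2.23e-07), from 5581 ± 1130 to 124 ± 26.9, and nos fell by 2.77 ± 0.34 (4.25e-05), bcd by 0.95 ± 0.21 (0.00247), CycB by 0.64 ± 0.19 (0.0146) and cid by 2.43 ± 0.33 (0.000104). RpL11 (1.76 ± 0.44, 0.00606) and RpL32 (1.70 ± 0.64, 0.0431) rose, as did the replacement histone His3.3B (1.61 ± 0.27, 0.000412), while mt:CoII was at 1.51 ± 0.53 (0.0331, 0.0763 with the preparation block). The gap gene hb (0.35 ± 0.67, 0.696) and zld (0.36 ± 2.12, 0.907), both also loaded by the mother, did not pass.

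By list in the input, 32 of 34 early zygotic short genes, 28 of 32 dorsoventral genes, 13 of 14 segment polarity and Hox genes, 12 of 15 gap, terminal and head genes and 9 of 9 pair-rule genes rose (32, 29, 13, 12 and 9 adjusted over the list alone). In turn 8 of 8 pole cell genes, 18 of 35 maternal patterning genes and 14 of 27 maternal cell cycle genes fell, the same adjusted over the list alone, with 1 patterning and 7 cell cycle genes higher. Ribosomal protein genes rose in 57 of 86, 61 adjusted over the list alone (median 1.36, 0.81 on values scaled by their total alone and 0.09 as deposited, where all genes lay at −0.76). Camera called 12 lists, these 9 among them (adjusted p from 3.13e-10 to 0.00296), all lost (adjusted p = 0.262 to 0.676 with an estimated correlation). Limma called 2404 genes higher and 1868 lower. As deposited, these were 1171 and 2791, and on values scaled by their total alone 1225 and 2427.

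Whether enrichment itself differed between stages was tested as the difference of eluate over input. From NC 9-10 to cellular blastoderm it rose for the centromere histone cid (log2 2.72 ± 0.47, SE; adjusted p = 0.00284), the piRNA factor cuff (4.32 ± 0.71, 0.00249), CR45940 (4.09 ± 0.46, 0.00129), Cks85A (3.17 ± 0.82, 0.0127), msl-2 (2.96 ± 0.84, 0.0189) and trbl (2.89 ± 0.53, 0.00331). It also rose for Dfd (2.55 ± 0.79, 0.0268), tok (2.54 ± 0.48, 0.00376) and bowl (2.50 ± 0.44, 0.00294), whose direction turned on values as deposited when taken relative to all genes, which lay at 1.62 there. It fell for bcd (−1.44 ± 0.29, 0.00487), snk (−2.21 ± 0.59, 0.0143), the receptor of the termini tor (−2.09 ± 0.48, 0.00789), osk (−1.91 ± 0.51, 0.0151) and RpL10 (−1.89 ± 0.66, 0.0439). The early genes sisA (−2.60 ± 1.09, 0.0827), CG18269 (−2.47 ± 1.11, 0.101) and Brd (−2.74 ± 1.35, 0.131) and the maternal nos (−1.15 ± 0.48, 0.0811) did not pass, but did with the preparation block (0.015, 0.0193, 0.025 and 0.0105). Both nullo (−2.29 ± 1.30, 0.189) and zen (−0.85 ± 0.97, 0.523) did not pass. In all 2330 genes were higher and 744 lower, 3305 and 1587 with the preparation block and 2578 and 0 on values as deposited. Without the second NC 9-10 preparation none was called.

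From NC 9-10 to syncytial blastoderm, enrichment rose for the cell death gene rpr (4.49 ± 0.60, adjusted p = 0.00221), the hindgut gene byn (4.39 ± 0.54, 0.00221) and opa (4.13 ± 0.52, 0.00221). It rose as well for msl-2 (4.37 ± 0.84, 0.00953), Uhg5 (4.32 ± 0.67, 0.00343), ptc (3.87 ± 0.53, 0.00226) and the neuroectoderm gene vnd (3.75 ± 0.45, 0.00221). Further rises were those of wg (3.58 ± 0.51, 0.00258), slam (3.54 ± 0.53, 0.00312), grh (3.07 ± 0.80, 0.0441) and the head gene ems (4.18 ± 0.61, 0.00277), the last with its direction turned on values as deposited when taken relative to all genes, which lay at 0.52 there. It did not differ detectably for sisA (−0.33 ± 1.09), nullo (−0.36 ± 1.30) or zen (1.39 ± 0.97, 0.804). The lower genes were the non-coding CR44267 (−2.90 ± 0.59, 0.0125) and vir-1, which responds to viruses (−1.60 ± 0.43, 0.0494). Limma called 498 genes higher and 2 lower, 686 and 18 with the preparation block, 11 and 0 on values as deposited, and none without the second NC 9-10 preparation.

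The dose of 5-EU was tested at syncytial and cellular blastoderm, where each stage has 1 preparation per dose. Dose and preparation therefore cannot be told apart. The non-coding CR46024 was more enriched at 250 mM (adjusted p = 0.00844, 0.0538 with the preparation block). Enrichment was also higher at 250 mM for l(3)mbn (log2 2.99 ± 0.33, SE; adjusted p = 0.0379), the cuticle gene Pcp (2.23 ± 0.30, 0.0445), insb (2.04 ± 0.23, 0.0379) and CG5177 (2.01 ± 0.28, 0.0445). It did not differ detectably for zen (0.22 ± 0.81), sisA (0.23 ± 1.02), nullo (0.24 ± 1.12), bcd (0.18 ± 0.25) or mt:CoI (0.67 ± 0.78), all at adjusted p = 1. Limma called 6 genes higher and 6 lower, and none with the preparation block (adjusted p = 0.113 for the other 4 genes) or on values as deposited. Of 22 lists tested for dose, camera called 4. The 86 ribosomal protein genes had a median of −0.72 (camera 2.43e-15; adjusted p = 0.897 with an estimated correlation). Above the other genes lay the lists of 14 segment polarity and Hox genes (13 above 0, median 0.28, camera 0.0111; adjusted p = 0.897 with an estimated correlation) and 34 early zygotic short genes (30 above 0, median 0.28, camera 0.0384; adjusted p = 0.927 with an estimated correlation). So did that of 3 follicle cell genes (2 above 0, both called adjusted over the list alone, median 0.96, camera 0.0111, fry 0.0111; adjusted p = 0.392 with an estimated correlation). No gene of the 4 lists was called over all genes.

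Genes enriched at syncytial blastoderm were compared with the other tested genes in length and introns, using 8565 genes with an annotation. The 963 enriched genes had a median span of 2898 bp against 2508 bp (two-sided permutation test, p = 0.00059, adjusted 0.000738), and 21.2% of them were intronless against 11.6% (Fisher's exact test, odds ratio 2.04, p = 4.53e-15, adjusted 1.51e-14). Split by level in the NC 7-9 input, the intronless shares were 24.5% against 24.3% below 1 (Fisher's exact test, p = 0.957) and 10.6% against 9.19% at 1 or more (p = 0.483), so the share did not differ detectably within either class. By exonic length the difference did not pass (2043 against 1953 bp, permutation test, p = 0.203), nor did span for genes at least 2-fold enriched (2731 against 2517 bp, permutation test, p = 0.0526, adjusted 0.0584). Split by level in the NC 7-9 input, the spans were 2398 against 1744 bp below 1 and 4326 against 2662 bp at 1 or more (permutation test, p = 1e-05 for both). At cellular blastoderm the 3300 enriched genes spanned a median of 2791 bp against 2362 bp (p = 1e-05, the smallest the permutations can give) and 13.2% against 12.4% were intronless (Fisher's exact test, p = 0.301). Of those below 1 in the NC 7-9 input, 20.2% against 35.3% were (Fisher's exact test, p = 1.03e-11). Genes are not independent replicates in these tests, and at NC 9-10 no gene was called to compare.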

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

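The tests on the resemblance of inputs to poly(A) libraries and on genes lower in second preparations were chosen only after the result was seen, while the matching of ribosomal protein genes on length and level was written before its result was seen.

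Enrichment over input differed between NC 9-10 and cellular blastoderm in 3074 genes and between NC 9-10 and syncytial blastoderm in 500, by the test of the difference itself. Both counts were 0 without the second NC 9-10 preparation, and the second was 11 on values as deposited. The genes cid, trbl and msl-2 were among the genes more enriched at cellular blastoderm. It differed between 250 and 50 mM in 12 genes, among them Pcp and l(3)mbn, and in none with the preparation block.

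Of the 12 libraries labelled rRNA-depleted, the inputs of NC 9-10 and syncytial blastoderm held the mitochondrial large ribosomal RNA, which is polyadenylated, at 50320 and 51700 ppm, against 315 to 2821 in the other 10. For the candidate explanation that these are poly(A) libraries under another label, the lower of their correlations with a poly(A) input across genes was 0.989, and the highest of the other 10 with any poly(A) library was 0.942. These correlations are part of the resemblance itself and so are not a separate test. The NC 9-10 input was closest to the poly(A) input of the second NC 9-10 preparation. Failed removal of ribosomal RNA alone is argued against, because without ribosomal RNA genes the correlation with their own flow-through was lower by at least 0.0611 and was at most 0.935. A property of these stages is argued against too, because the transcript was at least 29.5 times as high in the input as in the flow-through of the same preparation. Of biological explanations only the stage was tested.

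A set of 309 genes, among them the corepressor gene Smr (log2 4.52 at NC 9-10 and 3.14 at the later stages), was more than 2-fold lower in the second poly(A) preparation in all 6 pairs of syncytial and cellular blastoderm libraries, where 2 genes were higher (209 of the set were lower in all 3 NC 9-10 pairs too, as were 443 of all 8618 genes). The dose of 5-EU alone is argued against, because at NC 9-10, where both preparations had 250 mM, their median difference was 1.73 (quartiles 0.95 and 2.89, positive in 301). Later embryos in the second NC 9-10 preparation are argued against, because the 1836 genes of level 5 or more that fell in the input towards cellular blastoderm were not lower in its input: first minus second, their median was −0.25 (quartiles −0.42 and −0.07, positive in 362), against −0.07 over all genes. Transcript length alone is argued against, because other genes of the same length differed by −0.12 at NC 9-10, although the set is long (median exonic length 5454 against 2080 bp) and length tracked the difference at the later stages (rank correlation 0.558 across genes). A difference in library preparation or RNA quality stays open as a possible source, untested, and it reaches zld, whose NC 9-10 inputs were at 421 and 9.18.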

How the results depend on the processing

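Alternatives added after the data were seen are scaling by the total alone, leaving out the second NC 9-10 preparation, leaving out the 2 rRNA-depleted inputs that resemble poly(A) libraries, and exonic length. The others were planned. The tests on other splits of the libraries were chosen only after the result was seen. Of 403 named gene results, 297 passed their test, and 145 of those passed under every alternative in which a lost call was counted. On values as deposited only a change of direction was counted, so calls lost there are missing from this number and the next ones. In all 618 of 4695 alternatives of called genes lost the call (95 with 250 mM libraries alone, 49 without the second NC 9-10 preparation and 48 without the second cellular blastoderm input), 103 alternatives gained one and 4 reversed. The reversed ones are values as deposited, relative to all genes: the differences in enrichment became −0.013 for Dfd, −1.28 for tok and −1.75 for bowl at cellular blastoderm and −0.036 for ems at syncytial blastoderm, and the cause was not tested. Eluate against input at cellular blastoderm (4845 genes), flow-through against input (0) and both comparisons of cellular blastoderm with NC 9-10 (4895 in eluates, 4272 in inputs) stayed within 1.5 times in total under every alternative run. By direction they did not: as deposited, eluate against input at cellular blastoderm had 61 higher and 4371 lower (3328 and 1517), the eluates 690 lower (1552) and the inputs 1171 higher (2404).

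With the replicate block (the preparation), the called genes were 38 at NC 9-10 (0 without it), 1682 at syncytial blastoderm (1034), 4892 for the difference in enrichment at cellular blastoderm (3074) and 0 for dose (12). It changed 6 list calls, and 9 named gene calls were lost, 5 of them for dose. On values as deposited, where the per-library factor shifts all genes, the counts were 6786 at NC 9-10, 6411 at syncytial blastoderm, 6909 over all stages (1426) and 6944 in rRNA-depleted RNA (0). They were 670 between syncytial and NC 9-10 eluates (1810), 11 for the difference in enrichment at syncytial blastoderm (500), 0 for dose and 9 at NC 7-9 (17). On values scaled by their total alone they were 9 at NC 9-10, 17 in rRNA-depleted RNA and 1 for dose. A pseudocount of 0.1 gave 10 at NC 9-10, 760 over all stages, 23 in rRNA-depleted RNA, 331 for the difference at syncytial blastoderm and 1 for dose. One of 5 gave 32 for dose. Without a filter there were 6 at NC 9-10, 278 over all stages and 99 for dose. For dose a filter of 5 gave 1, and no mean trend gave 3. A 2-fold minimum gave 852 over all stages. Flow-through as comparator gave 3 at NC 9-10, 3027 over all stages and 38 in rRNA-depleted RNA. With 250 mM libraries alone there were 0 over all stages, with fewer samples, and 920 for the difference at syncytial blastoderm. Without the second NC 9-10 preparation, which leaves 1 library per fraction there, 906 remained between syncytial and NC 9-10 eluates and 0 for both differences in enrichment. At NC 7-9 a minimum of 1 gave 49 and of 20 gave 6, and camera with an estimated correlation called 0 of the 97 lists. The log10 difference in length at syncytial blastoderm (0.063) was 0.02 by exonic length and 0.036 for genes at least 2-fold enriched. The cause was not tested.

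Leaving out 1 library at a time, the lone library left being assumed to vary like the others, gave 0 to 36 genes at NC 9-10 (5 and 36 without the first and second eluate) and 639 to 1261 at syncytial blastoderm (639 and 659 without the first and second input). Over all stages it gave 85 to 2261, and 13 of the 14 eluates and inputs moved the 1426 by more than 1.5 times. It was 2261 and 2204 without the NC 7-9 and first NC 9-10 eluate, 174 and 688 without the syncytial and 224 and 174 without the cellular blastoderm eluates (first and second). It was 541 without the NC 7-9, 523 and 178 without the NC 9-10, 333 and 93 without the syncytial and 238 and 85 without the cellular blastoderm inputs. In rRNA-depleted RNA it gave 0 to 47 (47 without the NC 7-9 preparation). For the difference in enrichment at cellular blastoderm it gave 1896 to 2956, lowest without the first cellular eluate, with 1999 and 2026 without the second NC 9-10 and second cellular blastoderm input. At syncytial blastoderm it gave 236 to 690, with 266 without the second NC 9-10 eluate, 242 and 238 without its inputs, and 236 and 330 without the syncytial inputs. For dose it gave 0 to 385: 110 and 132 without the syncytial and 384 and 385 without the cellular eluates, and 0 without either cellular input. Over all 7 preparations the real split called 1426 genes and 1 of 100 drawn splits, the real one, gave as many (the highest other 156). Of 64 splits that exchange eluate and input within preparations, again only the real one did (the highest other 0). Other groupings did not reach the count, but its size depends on single libraries, as given above. For flow-through against input and for rRNA-depleted RNA the real count was 0, so all 100 and all 35 splits give as many by construction, which says nothing about chance. The highest other split called 695 genes for flow-through against input and 2 for rRNA-depleted RNA. Among splits within preparations the highest other count was 0 for both, so the 695 arose only where preparations were broken up. The source was not tested. Estimated depth of 1.93 M to 36.9 M reads limits genes near the added 1, where the pseudocount sets the ratio.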

Other observations

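The tests of ribosomal protein genes against genes of the same length or level over all stages were written before their results were seen; the tests against maternal lists and on length at cellular blastoderm alone were chosen only after the result was seen.

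Transcripts of the mitochondrial genome formed the other large class in labelled RNA. At NC 7-9 mt:CoI was at 10940 ppm in the poly(A) eluate and 3783 in the input, and the median log2 ratio of the 15 genes was 1.37 in poly(A) and 2.12 in rRNA-depleted RNA. In rRNA-depleted RNA it was 4.71 at NC 9-10 and 4.03 at syncytial blastoderm, where the inputs resemble poly(A) libraries, and at cellular blastoderm it was below the NC 7-9 value. The median share of their deposited values found in the poly(A) eluate was 10.6% at NC 7-9, 17.6% and 5.22% at NC 9-10, 47.7% and 32.1% at syncytial blastoderm and 27.6% and 23.3% at cellular blastoderm (first and second preparation). For all genes it was 6.36%, then 3.42% and 5.00%, 11.4% and 9.61%, and 22.6% and 24.4%, so the second NC 9-10 and the cellular blastoderm preparations were close to the bulk. The NC 9-10 preparations differed: mitochondrial enrichment was 2.66 higher in the first (all 15 genes), and the input held less there (−1.65).

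Some genes already present in the NC 9-10 input were far higher in the eluate at syncytial blastoderm. The gap gene hb was at 203 ± 77.0 (SD, n = 2) in the NC 9-10 eluate and 2059 ± 1730 in the syncytial one, while its input was at 189 ± 34.1 and 157 ± 96.5. The eluate level of slam was 177 and 108 in the NC 9-10 preparations and 6645 and 5139 in the syncytial ones. Its input level was 111 and 79.1 and then 334 and 345, so the input rose as well, by less. The rRNA-depleted eluate of NC 9-10 held the short genes CG13712 at 504 and CG18269 at 478 ppm, against inputs of 1.23 and 1.41. At syncytial blastoderm the non-coding CR45916 was at 556 against 1.03 in the input and 0.923 in the flow-through. Both inputs resemble poly(A) libraries, and with 1 library per group there was no test.

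Ribosomal protein mRNAs lay below the bulk of genes in the poly(A) eluate (median log2 −1.08 over all stages), while 57 of 86 rose in the input towards cellular blastoderm. Maternal supply of the mRNA alone is argued against over all stages, because the 2 maternal lists had medians of −0.27 and −0.15 (lower quartiles −0.40 and −0.51) and 2 of their 62 genes lay at −1.08 or lower, but it stays open at cellular blastoderm, where the lists were at −1.14 and −0.46 (lower quartiles −1.49 and −1.19) against −2.05. Other genes of the same exonic length lay at −0.01, but they include early zygotic short genes (median 2.95), and among genes already in the NC 7-9 input, where longer transcripts were more enriched (rank correlation 0.43 across genes), they lay at −0.33, so length stays open. At cellular blastoderm these matched genes lay at −0.29 (quartiles −0.58 and −0.05), and genes matched on both length and level at −1.32 (58 genes). Over all stages genes of the same level lay at −0.32, and those matched on both at −0.60, so short length (median 903 against 1985 bp) and level may account for part of the difference.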
